A study of Mus musculus with 9 samples.

How the data were processed

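Gene expression was measured by RNA sequencing of the duodenum of male C57BL/6 mice, all kept on chow for 3 months. The labels give 4 controls (WT) and 5 mice carrying a mutation in Pla2g12b. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected, and complementary DNA was primed with random hexamers. Second strands were made with dTTP, so the libraries do not mark strand, and reads of overlapping or antisense genes cannot be told apart. HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used for alignment and counting, per the submitters' processing notes. Those notes name the builds GRCh37, hg19 and mm39, of which the first pair are human. The gene coordinates in the deposited table were compared with the GENCODE M21 annotation of GRCm38: of 54532 gene identifiers, 54495 were found there, all on the same chromosome, and 53585 had the same start and end. Coordinates are therefore given as GRCm38, as in the deposited table. The annotation release, strand setting and handling of reads shared by several genes are not given in the sources used here. Counts of near-identical genes, such as the trypsinogens Try4 and Try5, the defensins, the gasdermin C genes and immunoglobulin segments, are therefore uncertain.

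The authors deposited raw read counts per gene, without normalization, for the 9 libraries. All per-sample columns were used. Total counts ranged from 16119639 to 24009157 per library, so 3 reads correspond to at most 0.186 CPM, read counts scaled to a common library size. Intervals and floors from read counts cover counting error only, since the libraries carry no molecular identifiers. The table stored 27 gene symbols as dates, and their names were taken from a reference table by gene identifier. Of 1010 gene list entries, 1009 were matched by symbol, and 1 T cell entry was not.

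Libraries were grouped by the genotype in the labels. The comparison was mutant against WT, tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the counts (TMM scaling, the tool's default expression filter, robust dispersion, genotype as the only term). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 15416 genes that passed the filter. Every adjusted p of a gene is from this test unless another fit is named. Log2 fold changes are mutant over WT and are given with their standard error (SE). The SE is the coefficient's size divided by the square root of the test statistic, and none is given for genes with 0 reads in a group. CPM are on TMM-scaled library sizes. Shares of reads per library and log2(CPM + 1) of Pla2g12b on unscaled totals were compared by 2-sided exact permutation over all splits into 4 and 5 libraries.

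Before the data were examined, 53 gene lists were written from textbook knowledge of intestinal function, the cell types a duodenal sample can hold, and sample quality. For each list the called members were counted over all genes tested and again adjusted over the list alone. Lists with at least 5 tested genes, 51 of them, were compared with all other genes by camera of limma 3.58.1 (preset correlation of 0.01, log2 CPM with a prior count of 2). Camera with an estimated correlation and fry, a rotation test that does not compare a list with other genes, were run beside it. The rule for naming genes was also fixed then: Pla2g12b, a panel of lipid-absorption genes, the 10 higher and 10 lower called genes with the largest fold change, and up to 4 called members per list by smallest p. The ranked genes needed a mean of at least 1 CPM and no overlap between the groups, and predicted genes, pseudogenes and receptor segments were left out. Genes chosen after their values were seen are P4hb, Gpam, Acadm, Itgam, Fbln1, Spink1, Neurod1, Cpe, Slc40a1, Dbp, Ins1, Ins2, Cyfip2, Ide, Wdfy1 and Retnlb. Of these, Neurod1 is not reported further. Some genes that the rule names are not reported here.

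Alternatives fixed in advance were relative log expression factors, library size alone, no filter, a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, voom with sample quality weights, no robust dispersion, the mouse number as a block, 1 surrogate variable (sva 3.50.0), removal of acinar and immunoglobulin genes, and leaving out each library. Libraries were then compared with each other. In 4 pairs (WT 1 and 2, WT 3 and 4, mutant 2 and 3, mutant 4 and 5) the counts were much closer than in the other pairs of a genotype, though slightly further apart than sampling alone gives. Since the labels number separate mice, all 9 libraries stayed in the comparison. Added after this was seen were a fit to summed counts of each close pair (2 WT units against 3 mutant units), a voom fit with the pair as a random block, and fits leaving out each pair. The mouse numbers did not pair the genotypes.

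The calling steps were tested on simulated data with the real library sizes and dispersion. Each simulated library was drawn independently, so the recovered shares and false calls do not cover close pairs. With 9 libraries (15141 genes), 26.9% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, with 9 false calls. With close pairs summed (16937 genes) the recovered shares were 1.49%, 35.8% and 62.1%, with 12 false calls. A simulated shifted list was called by camera and 0 other lists were.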

Results

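Duodenal RNA was sequenced in 9 libraries, which the labels give as 4 WT and 5 Pla2g12b mutant mice. PLA2G12B is a member of the secreted phospholipase A2 family that lacks catalytic activity and acts in the loading of lipoproteins with lipid. The series title links the gene to intestinal lipid absorption and names the substitution C129Y as dominant negative, but the sample labels do not say which change the mutant animals carried. Total counts per library were 16119639 to 24009157 in WT and 16245982 to 17959658 in mutants. The first principal component, with 69.2% of the variance, separated the genotypes, and the second, with 12.4%, separated libraries within them.

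**Figure D1:**
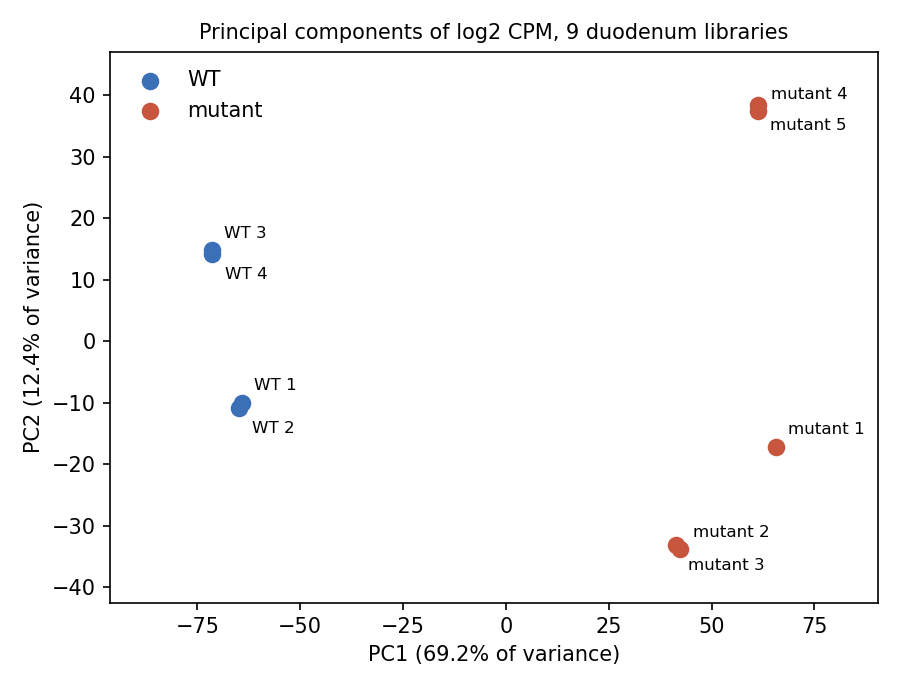
First (x) and second (y) principal components of log2 CPM over all tested genes, 1 point per library, with the share of variance on each axis. WT libraries lie at -71.5 to -64.2 on the first component and mutant libraries at 41.2 to 65.6, and 4 pairs of libraries nearly coincide.

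Within each genotype, libraries fell into close pairs: WT 1 with 2, WT 3 with 4, mutant 2 with 3 and mutant 4 with 5, with mutant 1 apart. The biological coefficient of variation within these 4 pairs was 0.0373 to 0.0504, against 0.178 to 0.254 in the other 12 pairs of the same genotype. The chi-square per degree of freedom of their counts was 2.37 to 3.43, against 34.5 to 70.1. The pairs thus differed more than sampling noise alone gives, which does not tell separate animals from repeat libraries of 1 animal. V segment use, given under other observations, was as alike in these pairs as would be for 1 animal. They were kept as separate libraries because the labels number the mice separately, and n counts libraries throughout. If 2 libraries of a pair share an animal, p-values over 9 libraries overstate the precision, so the counts of higher and lower genes, over all genes and per list, are given also with close pairs summed, which leaves 2 WT and 3 mutant units.

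Pla2g12b itself (ENSMUSG00000009646, a protein-coding gene on chromosome 10, 59403660 to 59421976, plus strand, GRCm38) was transcribed in every library. Its level was 90.1 ± 15.7 CPM in WT (SD, n = 4) and 120.9 ± 15.1 CPM in mutant duodenum (SD, n = 5), a log2 fold change of 0.42 (SE 0.13). The edgeR adjusted p was 0.023, and the exact permutation p was 0.0159. Both treat the 9 libraries as independent, and a permutation with close pairs as units could not go under 0.1. WT libraries 1 and 2 held 103 and 104 CPM and WT 3 and 4 held 77.5 and 75.6 CPM, while the mutant libraries ranged from 102 to 134 CPM. The call was lost with close pairs summed (adjusted p = 0.14), without WT 3 (0.076), WT 4 (0.075), mutant 1 (0.054), mutants 4 and 5 (0.088) or WT 3 and 4 (0.24). A transcript level does not check a change of a single amino acid.

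Over the whole transcriptome, 2369 genes were higher and 2634 lower in mutant duodenum. Among them, 189 rose and 1606 fell by more than 1 on the log2 scale. With close pairs summed the counts were 385 higher and 1173 lower, of which 379 and 1102 had been called in the same direction over 9 libraries. With the pair as a random block they were 1172 and 1644, of which 1160 and 1617 had been. Without WT 3 and 4 they were 1451 and 1975. Of 169 genes named or listed for naming, some of which had no call over 9 libraries to lose, 66 lost their call with close pairs summed and 41 without WT 3 and 4.

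The 10 lower genes picked by the naming rule, which leaves out predicted genes and those the deposited table marks as pseudogenes, were all products of the exocrine pancreas. They were the elastases Cela3b and Cela2a, the proteases Ctrb1, Try5, Try4, Prss2 and Cpa1, the lipases Pnlip and Cel, and Reg2. Ctrb1 held 13161.7 ± 5800.5 CPM in WT (SD, n = 4), and 6 reads over the 5 mutant libraries. Its WT-to-mutant ratio was 179596, with a 95% counting interval of 82512 to 489386. Pnlip, pancreatic lipase, held 5927 CPM in WT and 7 mutant reads. Reg2 held 222 CPM in WT and 0 reads in the mutants, which makes it at least 6036-fold lower at a floor of 3 reads over the group. Its place among the 10 rests on a fitted value that 0 reads do not bound. Of 26 tested genes of the acinar list, 25 were lower (25 adjusted over the list alone, 24 with close pairs summed), with a median log2 fold change of -12.9, or -12.5 with genes at 0 reads set to their bound (camera adjusted p = 1.6e-33; adjusted p = 0.17 with an estimated correlation). The only acinar list gene that rose was the trypsin inhibitor Spink1, by 0.98 (SE 0.11).

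The acinar list took 4.19% and 4.13% of reads in WT 1 and 2 and 8.56% and 8.49% in WT 3 and 4. It took 0.0445% to 0.0569% in the mutant libraries (exact permutation p = 0.00794, the smallest these 9 libraries can give). That is 7893 to 10031 reads per mutant library, while Ctrb1 and Pnlip held 6 and 7 reads over all mutants. The mutant share therefore comes largely from other genes of the list and does not measure pancreatic RNA. Mitochondrially encoded RNAs took 3.86% ± 0.128 of reads in WT and 6.32% ± 0.932 in mutants, and immunoglobulin genes 1.25% ± 0.0706 and 0.359% ± 0.166 (SD, n = 4 and 5; exact permutation p = 0.00794 for each). These permutations treat the 9 libraries as independent. With close pairs as units, no share of splits under 0.1 can be reached. Xist was at 2 to 15 reads and the Y-linked Ddx3y at 483 to 783 reads in all 9 libraries, as in males.

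**Figure D2:**
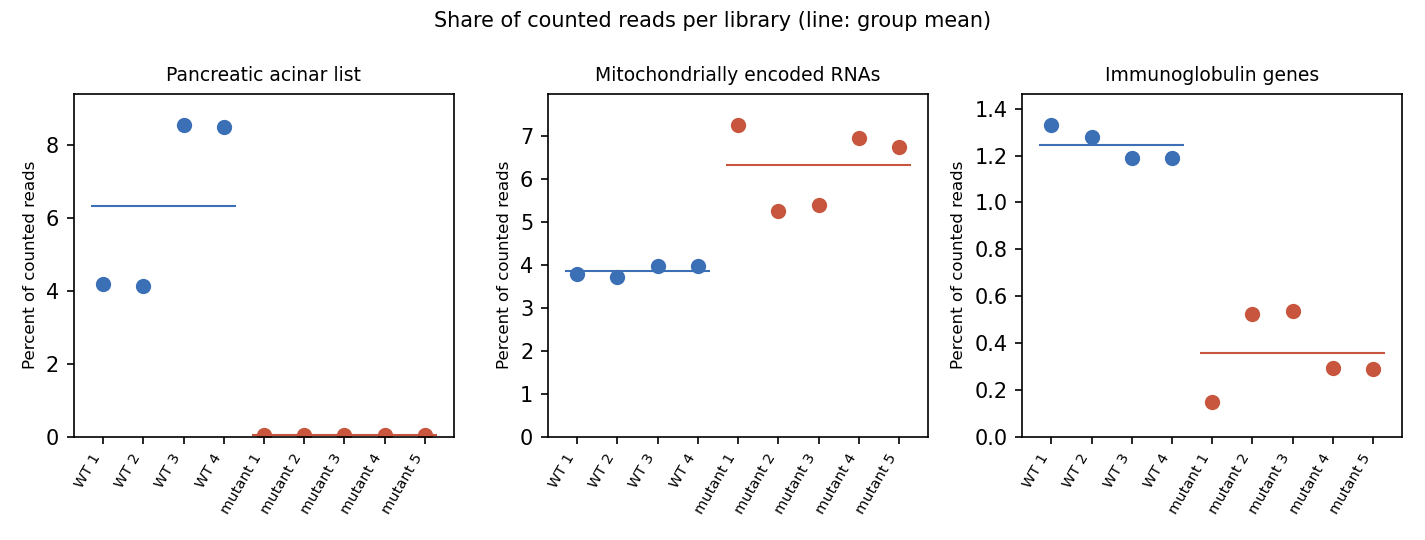
Percent of counted reads (y) taken by the pancreatic acinar list, the mitochondrially encoded RNAs and the immunoglobulin genes in each library (x), with a line at each group mean. The acinar share is 4.13% to 8.56% in WT and at most 0.0569% in mutant libraries.

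The comparison addresses lipid absorption, and 6 of the 12 genes of the panel fixed for it were called over 9 libraries. Apob, the structural protein of chylomicrons, had a log2 fold change of 0.17 (SE 0.12), Mttp, which transfers lipid onto it, 0.24 (SE 0.13), Apoa4 0.14 (SE 0.15) and Apoa1 0.38 (SE 0.17). The fatty acid transporter Cd36 was at 0.17 (SE 0.10) and Mogat2, which makes diacylglycerol, at 0.29 (SE 0.11). None of these was called. The fatty acid binding proteins Fabp1 and Fabp2 rose by 0.52 (SE 0.11) and 0.72 (SE 0.13), Dgat1, which completes triglyceride synthesis, by 0.60 (SE 0.11), the sterol transporter Npc1l1 by 0.42 (SE 0.09) and the chaperone Hspa5 by 0.46 (SE 0.08). Plin2, a lipid droplet coat protein, fell by 0.37 (SE 0.13, adjusted p = 0.046). With close pairs summed, none of the 12 was called, with adjusted p from 0.062 for Fabp2 to 0.61 for Apoa4. The Plin2 call was also lost without any of WT 1 to 4 or mutants 1 to 3, with adjusted p from 0.057 to 0.12, and with the pair as a random block (0.063).

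**Figure D3:**
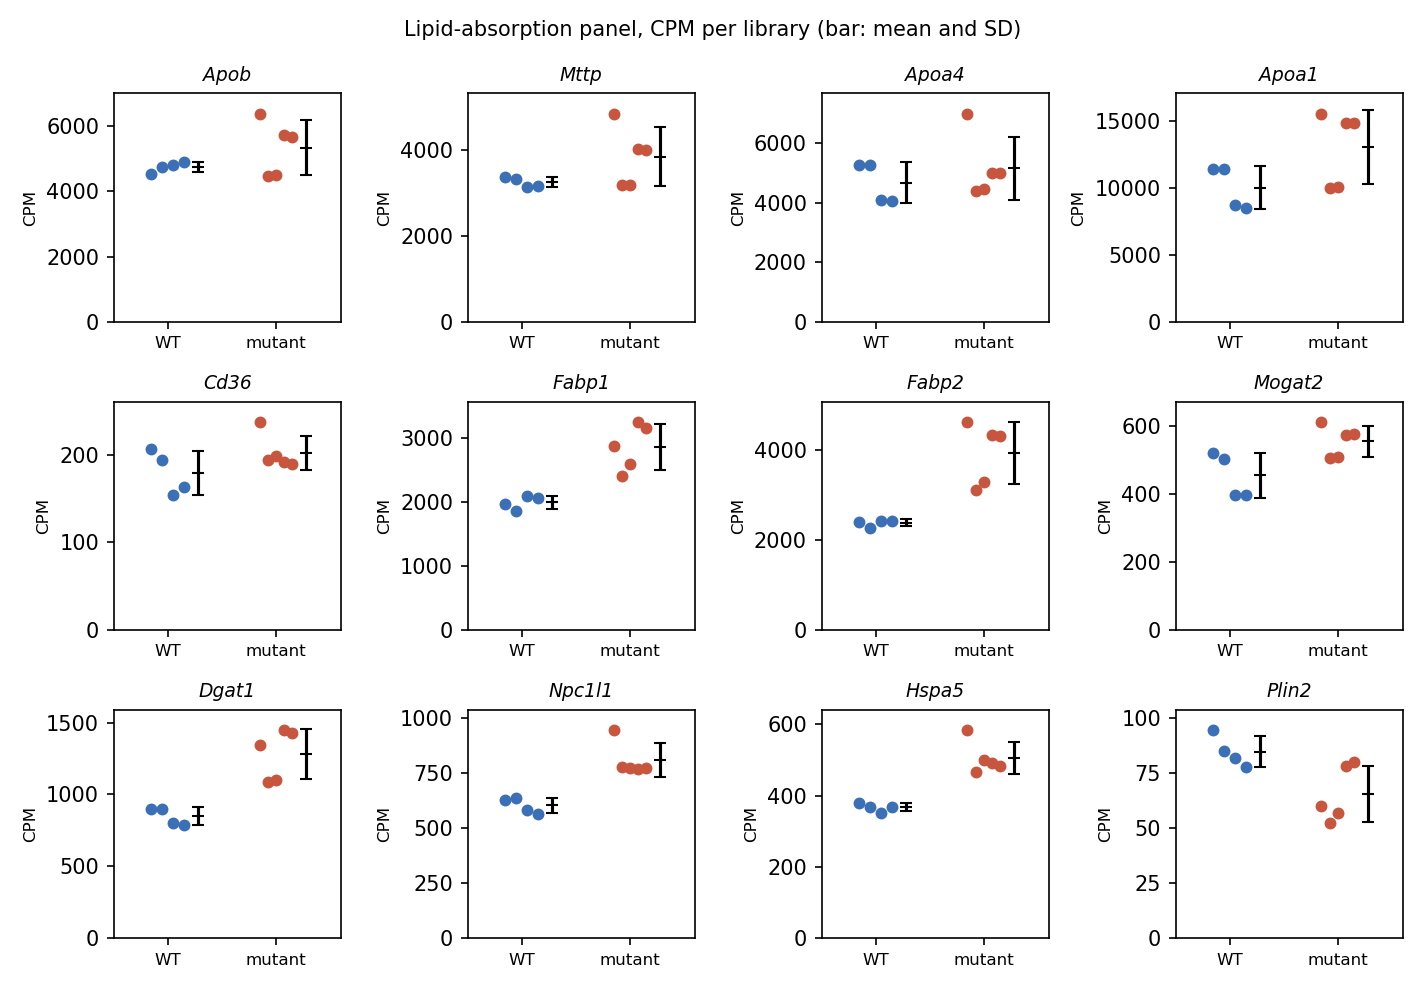
CPM (y) of the 12 panel genes in each WT and mutant library (points), with the group mean and SD beside them (n = 4 and 5). Fabp2 lies at 2261 to 2424 CPM in WT and at 3104 CPM or more in mutant libraries, while Apob values of the groups overlap.

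Most genes of cholesterol synthesis were higher. Of 25 tested, 20 were called higher and 0 lower (23 and 0 adjusted over the list alone, 6 and 0 with close pairs summed), with a median log2 fold change of 0.59 (camera adjusted p = 3.3e-08; adjusted p = 0.45 with an estimated correlation). The synthase Hmgcs1 rose by 0.98 (SE 0.13), the lanosterol demethylase Cyp51 by 0.99 (SE 0.15) and the methylsterol oxidase Msmo1 by 0.73 (SE 0.10).

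Other lipid lists held fewer calls. In lipoprotein assembly and secretion, 5 of 19 genes were higher and 0 lower (5 and 0 adjusted over the list alone, 1 and 0 with close pairs summed), with a median of 0.24 (camera adjusted p = 0.0042; adjusted p = 0.60 with an estimated correlation). They were Tmem41b at 0.58 (SE 0.07), Apoa2 at 0.86 (SE 0.22), Tm6sf2 at 0.31 (SE 0.09), the transcription factor Creb3l3 at 0.29 (SE 0.10) and the Mttp partner P4hb at 0.30 (SE 0.10). Lists matched to this list on gene length and expression had a median of 0.19. For triglyceride synthesis 3 of 15 were higher (Dgat1, Gpat3 and Acsl5) and 2 lower (Lpin1 and Gpam), 4 and 2 adjusted over the list alone and 0 with close pairs summed. In fatty acid uptake and binding, 3 of 9 were higher and 1 lower (3 and 1 adjusted over the list alone, 1 and 0 with close pairs summed). Dbi, which binds acyl-CoA, rose by 0.83 (SE 0.07), and the fatty acid receptor Ffar4 fell by 1.48 (SE 0.43). For sterol uptake and efflux 2 of 13 were higher, Npc1l1 among them, and 3 lower (3 and 3 adjusted over the list alone, 0 and 1 with close pairs summed). The lower ones were Mylip at -1.37 (SE 0.20), Abcg1 at -1.07 (SE 0.27) and Scarb1 at -1.63 (SE 0.52). Whether these falls lay in enterocytes or in other cell types was not tested. Camera called none of these last 3 lists. Leaving out 1 library ended the calls of Creb3l3 (WT 1, 3 or 4, mutant 2 or 3; adjusted p up to 0.092), P4hb (any WT, mutant 4 or 5; up to 0.107), Tm6sf2 (WT 3 or 4; up to 0.0645), Gpam (WT 1, 3 or 4, mutant 4; up to 0.063), Ffar4 (WT 1; 0.074) and Scarb1 (WT 3 or 4, mutants 1 to 3; up to 0.102). Without WT 3 and 4, Scarb1 was at -0.86 (adjusted p = 0.32). Leaving out that pair also ended the calls of Apoa2, Tm6sf2, Creb3l3, P4hb, Gpat3, Acsl5, Lpin1, Gpam and Abcg1 (adjusted p from 0.075 to 0.22).

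In 3 further lipid lists, calls went both ways. Among PPAR alpha targets and fatty acid oxidation, 1 of 28 was higher (Acadm) and 6 lower, the same adjusted over the list alone and 0 and 3 with close pairs summed. The thioesterases Acot1 and Acot2 were at -0.80 (SE 0.12) and -0.63 (SE 0.09), and Pdk4 at -0.44 (SE 0.10). In the lipid droplet list 1 of 21 was higher (Ces2e) and 4 lower (1 and 2 adjusted over the list alone, 0 and 2 with close pairs summed), among them the lipases Mgll, at -1.43 (SE 0.18), and Pnpla2, at -0.30 (SE 0.10). Of 16 fatty acid synthesis genes, 5 were higher and 3 lower (5 and 3 adjusted over the list alone, 1 and 2 with close pairs summed), with Me1 at 0.65 (SE 0.10), Slc25a1 at 0.40 (SE 0.07) and Acacb at -0.76 (SE 0.10). Camera called none of these lists. The Pnpla2 call was lost without WT 1 (0.114), WT 2 (0.102), mutant 3 (0.061), mutant 4 (0.069) or mutant 5 (0.077), and with the pair as a random block (0.094). It was also lost without WT 1 and 2, at -0.11 (0.39), and without mutants 4 and 5, at -0.23 (0.135).

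The unfolded protein response list was split, with 8 of 26 higher and 5 lower (9 and 5 adjusted over the list alone, 3 and 3 with close pairs summed) and no camera call. The secreted stress factor Manf rose by 0.66 (SE 0.06), while the sensors Ern1 and Ern2 were at -0.59 (SE 0.08) and -1.85 (SE 0.22) and Derl3 at -2.05 (SE 0.26). Derl3 is also in the plasma and B cell list (median -1.69), and Ern2 is expressed by goblet cells, whose list had a median of -1.35. Of 24 ER export genes, 3 were higher (Tmed2, Sec23b and Lman1) and 1 lower (Sec16a), the same adjusted over the list alone and 0 with close pairs summed. In the integrated stress response 4 of 19 were higher and 5 lower (4 and 6 adjusted over the list alone, 0 and 2 with close pairs summed), with Atf4 at 0.31 (SE 0.08), Vldlr at -1.74 (SE 0.29), Phgdh at -0.95 (SE 0.22) and Nupr1 at -5.47 (SE 0.45). Nupr1 is also in the Paneth list, and its log2 ratio between the WT pairs was 1.48, near the acinar median of 1.05. Phospholipases and phospholipid remodelling held 4 higher and 7 lower of 22 (4 and 7 adjusted over the list alone, 0 and 5 with close pairs summed). Pla2g2d was at -3.17 (SE 0.17), Lpcat2 was also lower, and the pancreatic Pla2g1b went from 137 CPM in WT to 1 read in the mutants. Whether Pla2g2d and Lpcat2 fell within enterocytes or with the lower immune lists (macrophage and dendritic cell median -2.16) was not tested.

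About as many digestive and transport genes of enterocytes were higher as were not called. Of 20 peptide and amino acid genes, 9 were higher and 0 lower (12 and 0 adjusted over the list alone, 1 and 0 with close pairs summed), with a median of 0.42 (camera adjusted p = 0.00023; adjusted p = 0.60 with an estimated correlation). The peptidases Dpp4 and Enpep rose by 0.88 (SE 0.13) and 0.83 (SE 0.19), and the peptide transporter Slc15a1 by 0.75 (SE 0.17). The list's camera call was lost without WT 3 and 4 (adjusted p = 0.056). In carbohydrate digestion and transport 9 of 17 were higher and 0 lower (9 and 0 adjusted over the list alone, 1 and 0 with close pairs summed), with a median of 0.37 (camera adjusted p = 0.0016; adjusted p = 0.55 with an estimated correlation). They included sucrase-isomaltase (Sis) at 0.82 (SE 0.20), ketohexokinase (Khk) at 0.69 (SE 0.08) and G6pc at 0.60 (SE 0.14). Lists matched to the carbohydrate genes on length and expression had a median of 0.22. Brush border and enterocyte maturity genes held 3 higher (Epcam, Myo1a and Espn) and 1 lower (Klf4) of 23, the same adjusted over the list alone and 0 with close pairs summed, without a camera call. The Espn call was lost without WT 3 (0.084) or WT 4 (0.080).

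For retinoid and fat-soluble vitamin handling 4 of 15 were higher and 3 lower (5 and 4 adjusted over the list alone, 1 and 2 with close pairs summed). Rbp2, the retinol binding protein of enterocytes, rose by 0.78 (SE 0.09) and Lrat by 0.69 (SE 0.17), while the retinoid enzymes Aldh1a2 and Cyp26b1 were at -1.53 (SE 0.30) and -1.88 (SE 0.35). The libraries mix cell types, and the macrophage, endothelial and fibroblast lists had medians of -2.16, -1.90 and -1.19. Which cells account for the lower Aldh1a2 and Cyp26b1 was not tested. Among bile acid genes 4 of 7 were higher (4 higher and 1 lower adjusted over the list alone, 0 with close pairs summed): Slc10a2 at 1.39 (SE 0.43), Slc51b at 0.53 (SE 0.12), Slc51a at 0.47 (SE 0.11) and Nr1h4 at 0.31 (SE 0.07). Camera called neither list. The first 3 of these bile acid genes and Amn were the 4 higher genes among 12 distal small intestine identity genes (4 and 0 adjusted over the list alone, 0 with close pairs summed), with a median of 0.52 (camera adjusted p = 0.034; adjusted p = 0.55 with an estimated correlation). That camera call was lost without WT 3 (0.092), WT 4 (0.070), mutants 4 and 5 (0.094) or WT 3 and 4 (0.22). The Slc10a2 call was lost without WT 2 (0.053), WT 3 (0.076), WT 4 (0.076) or mutant 3 (0.058), and that of Amn without WT 3 (0.056).

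Most nuclear respiratory chain genes were higher. Of 27 nuclear respiratory chain genes, 22 were higher and 0 lower (26 and 0 adjusted over the list alone, 8 and 0 with close pairs summed), with a median of 0.42 (camera adjusted p = 3e-10; adjusted p = 0.45 with an estimated correlation). Ndufa2 rose by 0.96 (SE 0.10) and Cox7b by 0.76 (SE 0.10). Mitochondrially encoded RNAs held 9 higher and 0 lower of 13 (11 and 0 adjusted over the list alone, 3 and 0 with close pairs summed), with a median of 0.77 (camera adjusted p = 5e-05; adjusted p = 0.53 with an estimated correlation), among them mt-Co3 at 1.09 (SE 0.15) and mt-Nd2 at 0.77 (SE 0.14). Ribosomal proteins held 18 higher and 0 lower of 34 (25 and 0 adjusted over the list alone, 0 with close pairs summed), with a median of 0.25 (camera adjusted p = 1e-07; adjusted p = 0.56 with an estimated correlation), with Rps24 at 0.59 (SE 0.09) and Rps14 at 0.51 (SE 0.09). Lists matched to the ribosomal genes on length and expression had a median of 0.28, and lists matched to the respiratory chain 0.24. Fold change fell with gene length, with Spearman's rho of -0.35 across 8631 genes with a mean of at least 10 CPM, which are not independent replicates.

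Tuft cell genes were higher in the mutants. Of 16 tested, 15 were higher and 0 lower (15 and 0 adjusted over the list alone, 13 and 0 with close pairs summed), with a median of 1.58 (camera adjusted p = 7.9e-10; adjusted p = 0.45 with an estimated correlation). Pou2f3, the transcription factor that specifies tuft cells, rose by 2.04 (SE 0.22), Rgs13 by 2.09 (SE 0.19), Sh2d6 by 1.95 (SE 0.16) and Avil by 1.79 (SE 0.17). The succinate receptor Sucnr1, of the same list, was among the 10 higher genes picked by the naming rule, at 2.44 (SE 0.31). The others were the gasdermins Gsdmc2, Gsdmc3 and Gsdmc4, the phospholipase Pla2g4c, the receptor Vmn2r26, Mgat4c, the monocarboxylate transporter Slc5a8, the protease Capn11 and the glutathione peroxidase Gpx2. Gsdmc2 held 0.260 ± 0.299 CPM in WT and 14.3 ± 10.7 CPM in mutants, and Gpx2 102 ± 23.5 and 516.8 ± 260 CPM (SD, n = 4 and 5). Gsdmc3 had 3 WT and 196 mutant reads, a WT-to-mutant ratio of 0.0174 with a 95% counting interval of 0.00356 to 0.0517. With close pairs summed, Pla2g4c, Gsdmc4, Mgat4c, Slc5a8 and Gpx2 lost their calls, with adjusted p of 0.15, 0.070, 0.12, 0.15 and 0.061, and Gsdmc2 stood at 0.0497. With the pair as a random block, Gsdmc2, Pla2g4c and Mgat4c lost theirs (voom adjusted p = 0.054, 0.21 and 0.061).

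Paneth and goblet cell genes were lower. Of 18 Paneth cell genes, 15 were lower and 0 higher (15 adjusted over the list alone, 13 with close pairs summed), with a median of -3.47 (camera adjusted p = 2.8e-09; adjusted p = 0.31 with an estimated correlation). Lysozyme Lyz1 fell by 4.61 (SE 0.36), from 955.5 ± 386 to 39.2 ± 12.9 CPM (SD, n = 4 and 5), and the defensin Defa22 was at -4.76 (SE 0.43). Of 17 goblet cell genes, 14 were lower and 0 higher (14 lower and 1 higher adjusted over the list alone, 10 and 0 with close pairs summed), with a median of -1.35 (camera adjusted p = 1.1e-07; adjusted p = 0.42 with an estimated correlation). Zg16 was at -2.95 (SE 0.21) and Fcgbp at -2.29 (SE 0.16). The Paneth genes Clps, Pnliprp2 and Nupr1 and the goblet gene Klk1 are also made by the pancreas. Their log2 ratios between WT 3 and 4 and WT 1 and 2 were 1.499, 0.75, 1.48 and 0.97, against a median of 1.05 for the acinar list. Stem cell genes held 4 lower (Cd44, Lgr5, Rnf43 and Tnfrsf19) and 0 higher of 15 (6 and 0 adjusted over the list alone, 1 with close pairs summed), with a median of -0.34 (camera adjusted p = 0.022; adjusted p = 0.60 with an estimated correlation), a call lost without mutant 1 (0.073), mutants 4 and 5 (0.094) or WT 1 and 2 (0.11). Enteroendocrine genes held 5 lower and 1 higher (Cpe) of 22, the same adjusted over the list alone and 2 and 0 with close pairs summed, with Tph1 at -1.75 (SE 0.26), Cck at -0.77 (SE 0.10) and Sct at -0.46 (SE 0.11). Camera did not call that list. The Rnf43 call was lost without WT 3 (0.058), WT 4 (0.061) or mutant 4 (0.051). It was also lost without WT 3 and 4, at -0.22 (0.25), and without mutants 4 and 5, at -0.41 (0.113).

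Of 6 tested Brunner gland genes, 5 were lower (6 adjusted over the list alone, 5 with close pairs summed), with a median of -2.33 (camera adjusted p = 4.7e-06; adjusted p = 0.12 with an estimated correlation): Egf, Ggh, Pgc, Fcgbp and Tff2. Tff2, whose ratio between the WT pairs was 1.37, fell from 110 CPM to 6 mutant reads, and Egf fell by 2.59 (SE 0.25). All 3 gastric genes tested were lower (3 adjusted over the list alone, 2 with close pairs summed), too few for a camera test.

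Immune and vascular genes were lower in the mutant libraries, in which the acinar list took 0.0445% to 0.0569% of reads, against 4.13% to 8.56% in WT. All 10 MHC class II genes were lower (10 adjusted over the list alone, 10 with close pairs summed), with a median of -2.20 (camera adjusted p = 7.9e-10; adjusted p = 0.29 with an estimated correlation). The invariant chain Cd74 was at -2.92 (SE 0.19), H2-Aa at -2.59 (SE 0.13), H2-Eb1 at -2.32 (SE 0.15) and H2-Ab1 at -2.26 (SE 0.09). Among macrophage and dendritic cell genes 15 of 19 were lower and 1, Itgam, higher (15 and 1 adjusted over the list alone, 14 and 0 with close pairs summed), with a median of -2.16 (camera adjusted p = 4.1e-08; adjusted p = 0.17 with an estimated correlation). The growth factor receptor Csf1r went from 71.0 ± 2.69 to 6.68 ± 2.25 CPM (SD, n = 4 and 5), C1qb was at -3.07 (SE 0.20) and Lyz2 at -2.61 (SE 0.12).

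Plasma and B cell genes held 13 lower of 14 (14 adjusted over the list alone, 8 with close pairs summed), with a median of -1.69 (camera adjusted p = 3.3e-08; adjusted p = 0.42 with an estimated correlation). Pou2af1 was at -2.74 (SE 0.25) and Ighm at -2.01 (SE 0.18). T cell and intraepithelial lymphocyte genes held 15 lower of 20 (17 adjusted over the list alone, 5 with close pairs summed), with a median of -1.25 (camera adjusted p = 6.4e-08; adjusted p = 0.53 with an estimated correlation). Cd4 was at -3.49 (SE 0.26) and Cd3e at -1.96 (SE 0.25). Interferon response genes held 11 lower of 31 (11 adjusted over the list alone, 5 with close pairs summed), with a median of -0.67 (camera adjusted p = 0.00059; adjusted p = 0.74 with an estimated correlation), led by Iigp1 at -2.61 (SE 0.23) and Cxcl9 at -2.70 (SE 0.33). Without WT 1 and 2 this median was 0.06 and the camera call was lost (adjusted p = 0.59), and fry did not call the list over 9 libraries (adjusted p = 0.070).

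Endothelial genes held 16 lower of 17 (16 adjusted over the list alone, 10 with close pairs summed), with a median of -1.90 (camera adjusted p = 6.7e-08; adjusted p = 0.45 with an estimated correlation), with Pecam1 at -1.94 (SE 0.24), Kdr at -2.18 (SE 0.25) and Flt1 at -2.09 (SE 0.25). Fibroblast and matrix genes held 11 lower and 1, Fbln1, higher of 18 (12 and 2 adjusted over the list alone, 3 and 0 with close pairs summed), with a median of -1.19 (camera adjusted p = 0.00035; adjusted p = 0.60 with an estimated correlation), with Col14a1 at -2.19 (SE 0.25) and Pdgfra at -1.77 (SE 0.30). Smooth muscle held 1 higher (Tpm1) and 0 lower of 18, and enteric neurons and glia 2 higher (Chat and Prph) and 0 lower of 17, the same adjusted over the list alone, with 0 and 1 higher with close pairs summed. Camera called neither of these. The Fbln1 call was lost without WT 3 (0.0505) or WT 4 (0.0526).

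**Figure D4:**
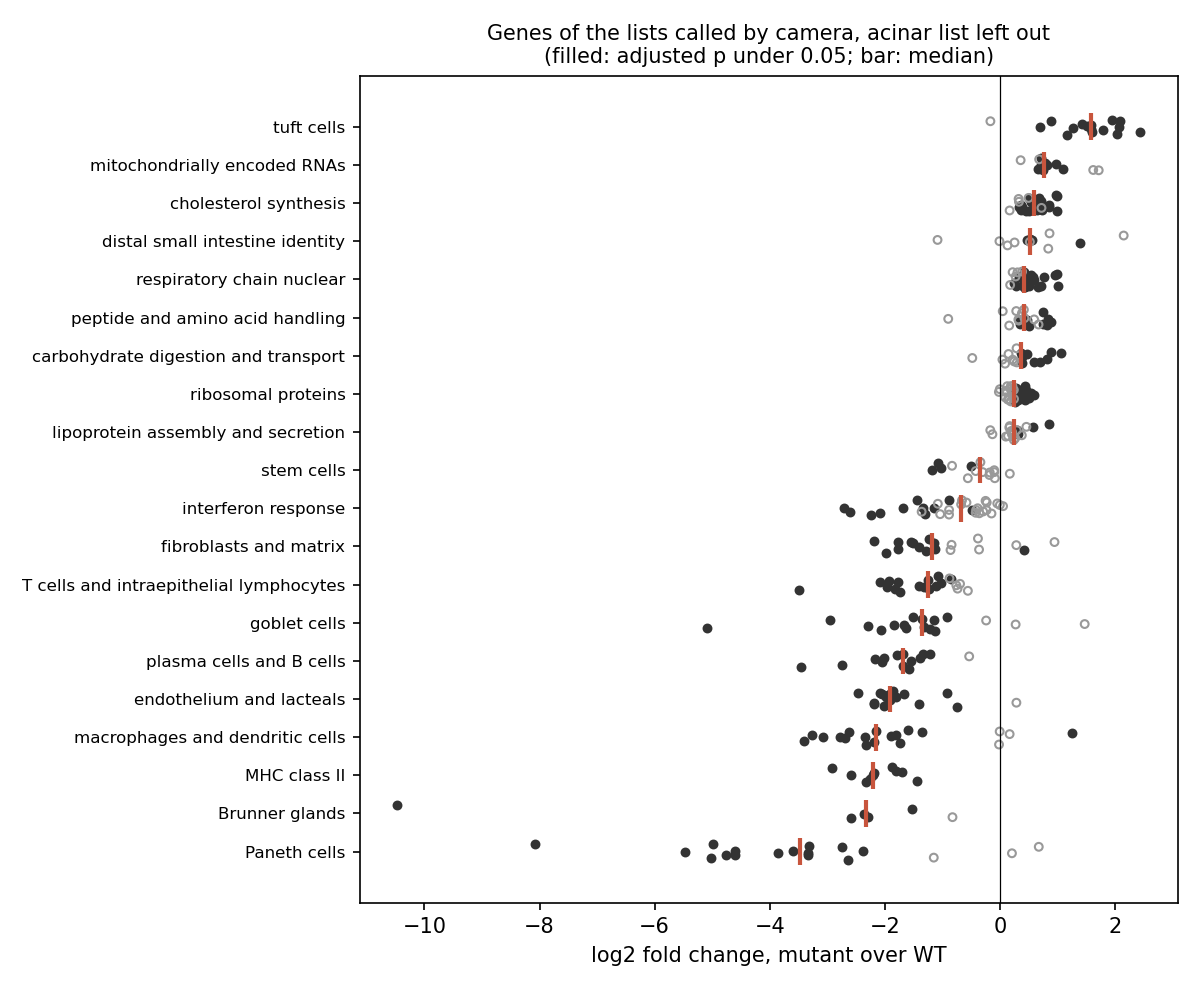
Log2 fold change, mutant over WT (x), of each tested gene of the 20 lists called by camera at its preset correlation, the acinar list left out (y, 1 line per list). Filled points had an adjusted p under 0.05, open points did not, bars mark list medians, and genes with 0 mutant reads are drawn at their bound. Medians run from -3.47 for Paneth cells to 1.58 for tuft cells.

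In all, camera called 21 of 51 lists, 9 up and 12 down. With an estimated correlation it called 0 after adjustment, 5 at an unadjusted p under 0.05, the smallest adjusted p being 0.12. Fry called 26, and camera with close pairs summed called 22, the same 21 lists and ER export (adjusted p = 0.045).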

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

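The results here were picked by the distance of 1 library from the others of its genotype, measured as the gap to the nearest library over the range of the group. Of 350 groups of values examined, 31 stood out, 6 in WT and 25 in mutants, where chance gives about 1 in 20 for independent libraries. The close pairs are not independent, so that share does not apply here. Mutant 1, the mutant library with no close partner, was the farthest in 14 of them, which the pairing of the other mutants favours. A gene with reads in only 1 library has a gap of 1 by construction.

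WT 1 was sequenced more deeply than the other WT libraries, at 24009157 counts against 16119639 to 16964882 (gap 0.893 of the range). Mutant 1 held the most Apoa4, at 6965 CPM against 4393 to 4992 (0.767), Cd36, at 237 against 189.7 to 198 (0.821), Npc1l1, at 946 against 770.4 to 779.8 (0.946), and Hspa5, at 584 against 466 to 500.4 (0.7101). It also held the most P4hb, at 5067 CPM (0.750), Sec23b, at 108 (0.826), Sec16a, at 136 (0.800), Slc51a, at 357 (0.840), G6pc, at 272 (0.797), and Myo1a, at 1703 (0.779). It held the least Zg16, at 161 CPM against 328 to 373 (0.788), Derl3, at 2.04 against 5.07 to 6.13 (0.740), H2-Aa, at 17.3 against 26.7 to 28.7 (0.828), and H2-Eb1, at 20.8 against 35.4 to 36.5 (0.926). Mutant 1 also had the lowest immunoglobulin share, at 0.151% of reads.

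Among pancreatic RNAs in the mutants, single libraries held a few reads. Mutant 4 held 0.0589 CPM of Cela3b, against 0 in the others (a gap of 1), and 0.294 CPM each of Ctrb1 (0.817) and Prss2 (0.799). Mutant 5 held 0.0577 CPM each of Try5 (1) and Pla2g1b (1), 0.173 CPM of Try4 (1), 0.115 CPM of Cel (1) and 0.289 CPM of Tff2 (0.796). Mutant 3 held 0.118 CPM of Cpa1 (1). These values rest on at most 5 reads in a library.

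WT 2 was lowest for Fabp2, at 2261 CPM against 2404 to 2424 (0.875), and Ern2, at 8.29 against 9.47 to 9.63 (0.884), and highest for Pla2g2d, at 9.97 against 9.36 to 9.38 (0.958). WT 1 was lowest for Cd44, at 22.2 CPM against 24.8 to 25.3 (0.832), and WT 4 highest for Cd4, at 14.1 against 12.7 to 12.8 (0.908). Mutant 2 was highest for Egf, at 0.753 CPM against 0.446 to 0.532 (0.720), and mutant 4 lowest for Abcg1, at 0.530 against 1.15 to 1.29 (0.810).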

How the results depend on the processing

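The fits to summed pairs, to the pair as a random block and without each pair were chosen after seeing the data. The Pla2g12b difference stayed above 0 in every fit, from 0.22 to 0.66 when libraries or pairs were left out and 0.46 with close pairs summed, where its adjusted p was 0.14. Genes called higher ranged from 1451 (without WT 3 and 4) to 2753 on leaving out libraries or pairs, and were 385 with close pairs summed and 1172 with the pair as a random block. Genes called lower ranged from 1975 to 2971, and were 1173 and 1644. Summing pairs leaves 5 units, and in simulated data it recovered 35.8% of genes changed 2-fold against 71.6%. The simulated libraries held no close pairs, so this does not tell how far fewer samples account for the fewer calls. The higher share of calls was 47.4% over 9 libraries, 40.05% with library size alone and 24.7% with close pairs summed. No alternative called a gene in the direction opposite to its call over 9 libraries. Lists called by camera ranged from 19 to 27 on leaving out libraries or pairs, and were 0 with an estimated correlation. The interferon response median turned to 0.062 without WT 1 and 2 (range -1.29 to 0.062). Apoa4, not called, turned to -0.0051 without mutant 1 and to -0.035 without WT 3 and 4 (range -0.035 to 0.34), Slc40a1, not called, turned to 1.27 without WT 3 and 4 (range -4.33 to 1.27), and Dbp, not called, to -0.32 in voom with sample quality weights. Ide, not called and near 0, turned to -0.019 with library size alone and -0.032 in that voom fit, and ranged from -0.024 to 0.087 on leaving out libraries or pairs. Wdfy1, not called, turned to -0.15 without WT 1 and 2 (range -0.15 to 0.73). The cause was not tested. Of 169 named genes, some of them uncalled over 9 libraries, 66 lost their call with close pairs summed, 41 without WT 3 and 4, 18 with the pair as a random block, and at most 14 in any other fit.

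The mouse number as a block gave 1890 higher and 2324 lower genes, 23 lists and a Pla2g12b difference of 0.41. The correlation of deviations between mice of the same number was 0.036, 0.14, -0.13 and 0.12, and only number 2 correlated best with its own number, so the numbers share only a label. Depth limits the fold changes of pancreatic genes, with 0 to 7 reads over 5 mutant libraries for those given as reads, and of higher genes with few reads over the 4 WT libraries: Gsdmc3 (3), Vmn2r26 (12), Capn11 (17), Gsdmc2 (23) and Mgat4c (24).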

Other observations

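The tests of shared animals, pancreatic RNA, non-epithelial share, enterocyte share and a type 2 response were chosen after the results were seen. Those of splits, the region around Pla2g12b, and gene length for the respiratory chain and ribosomal lists were set before their outcomes were known. Gene length in the other lists reported was examined because camera had called them.

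Further lists held scattered calls and no camera call. Antimicrobial and epithelial defence genes held 2 higher and 3 lower of 14 (2 and 3 adjusted over the list alone, 1 and 2 with close pairs summed): the antimicrobial lectin Reg3b rose by 1.65 (SE 0.45), a call lost without WT 3 (0.059) or WT 4 (0.058), and the fucosyltransferase Fut2 by 1.85 (SE 0.20), while the tryptophan-degrading enzyme Ido1 was at -3.21 (SE 0.42). In the mast cell and eosinophil list 1 of 5 was higher, Siglecf, which tuft cells also express, at 1.43 (SE 0.17), and 1 lower (1 and 2 adjusted over the list alone, 1 and 0 with close pairs summed). Xenobiotic metabolism held 4 higher and 3 lower of 27 (4 and 3 adjusted over the list alone, 1 and 2 with close pairs summed), with the aryl hydrocarbon receptor targets Cyp1b1 and Ahrr at -2.04 (SE 0.43) and -2.20 (SE 0.40). Oxidative stress and glutathione genes held 5 higher and 2 lower of 24 (5 and 2 adjusted over the list alone, 1 and 0 with close pairs summed), and iron, calcium and zinc handling 1 higher and 2 lower of 19 (0 and 2 adjusted over the list alone, 0 with close pairs summed). The heme oxygenase Hmox1, in both lists, was at -1.77 (SE 0.40), and which cells account for its fall was not tested.

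Cell cycle genes held 1 higher and 4 lower of 27, villus tip genes 2 and 3 of 15, villus base genes 2 and 0 of 13, adipocyte genes 1 and 2 of 12, and blood cell genes 0 and 1 of 4, the last too few for camera. Adjusted over the list alone these were 1 and 3, 2 and 3, 2 and 0, 1 and 2, and 0 and 1, and with close pairs summed 0 calls were left except 1 and 1 for adipocytes and 0 and 1 for blood cells. Proximal identity genes held 3 and 0 of 12, clock genes 1 and 0 of 17, immediate early and heat shock genes 5 and 3 of 23, histone genes 3 and 0 of 5, and the strain and sex check 1 and 1 of 7. Adjusted over the list alone these were 3 and 0, 0 and 0, 6 and 4, 3 and 0, and 1 and 1, and with close pairs summed 0 calls were left except 0 and 1 for immediate early genes and 1 and 1 for the strain and sex check. In this last list Cyfip2, a gene that differs between C57BL/6 substrains, fell by 2.06 (SE 0.17), with 16.7 to 21.1 CPM in WT and 3.31 to 5.95 CPM in mutants. The strain genes Ide, at 0.02 (SE 0.07), and Wdfy1, at 0.23 (SE 0.22), were not called, and their sign turns in some fits. The list also held the strain genes Nnt, Crb1, Entpd4 and Entpd4b, which are not reported here, and its gene called higher is not named. The median, mean and camera direction differed in sign for the uncalled lists of lipid droplets, unfolded protein response, retinoid handling, adipocytes, proximal identity, oxidative stress, xenobiotic metabolism and strain and sex, and median and mean did for blood cells.

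Some genes differed between close pairs more than between genotypes. The iron exporter Slc40a1 held 22.7 and 22.9 CPM in WT 1 and 2 but 353 and 351 CPM in WT 3 and 4, and 7.44 to 11.3 CPM in mutants 1 to 3 but 123 and 124 CPM in mutants 4 and 5. The clock output gene Dbp held 44.4 CPM in mutant 1, 27.7 and 25.6 CPM in mutants 2 and 3, 3.77 and 3.46 CPM in mutants 4 and 5, and 6.07 to 9.38 CPM in WT. The insulin genes Ins1 and Ins2 had 447 and 1628 reads over the WT libraries and 0 in the mutants, at least 170-fold and 618-fold lower at a floor of 3 reads over the group.

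The genotype split called more genes than the other splits drawn. Of 100 splits of the 9 libraries, the real one included, 1 gave as many as 2369 higher genes (highest other 1874) and 1 as many as 2634 lower genes (highest other 1353). The runner-up put 4 mutants against the WT libraries and 1 mutant, close to the real split. Most other splits broke close pairs apart, which the real split does not, so these shares cannot exclude chance for the genes. Nor was chance excluded for the lists: 32 of the 100 splits called at least 21 (highest other 26). Over summed pairs only 10 splits exist, and a share under 0.1 cannot be reached.

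The close pairs may each come from 1 animal. Antibody and T cell receptor V segments, whose use is private to an animal, differed within close pairs by a median of 1.15 times as much chi-square as other genes of the same level (0.997 to 1.72), against 10.6 times (6.14 to 14.7) in the other pairs of a genotype. The labels number the mice separately, and animals sharing a cage or dissection would not be expected to share V segments. Pooled or exchanged tissue would also give this, and was not tested.

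Between the 2 WT pairs, the immune, endothelial, Paneth and goblet RNAs lower in mutants did not, as a set, follow the pancreatic RNA. WT 3 and 4 held about 2 times the acinar RNA of WT 1 and 2 (median log2 ratio 1.05, lower quartile 0.93), but the 98 called-lower members of these lists had a median ratio of -0.11, and Paneth genes -1.60. Members also made by the pancreas did follow it: Clps at 1.499, Nupr1 at 1.48, Klk1 at 0.97 and Pnliprp2 at 0.75. This sets 1 pair against 1 pair, each perhaps from 1 animal. Differences between animals could therefore hide RNA that came with the pancreas. Not all non-epithelial RNA fell: smooth muscle and neuron genes had a median log2 fold change of 0.37, against -1.78 for macrophage, endothelial and lymphoid genes. What was dissected with the duodenum, its position, housing and microbiota, a difference in C57BL/6 substrain, and the genotype itself remain open and untested, and each may contribute.

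The rise of respiratory chain RNAs lay at percentile 99.96 of 10000 lists matched on gene length and expression, above their central 95%. That of ribosomal proteins lay at percentile 25.02, so it did not stand out from its matched lists. Only listed genes were left out of the matching, so unlisted ribosomal protein genes could be among the matches. The test therefore cannot tell gene length bias from a rise of ribosomal protein RNAs. Gene length bias could account for lipoprotein assembly (70.8) and carbohydrate genes (97.2), which lay within the central 95% of their matched lists. Cholesterol synthesis and tuft cells stood at 100. A larger share of enterocytes could also raise the respiratory chain (median 0.42, lower quartile 0.36): the peptide and carbohydrate lists stood at 0.42 and 0.37 and the brush border list at 0.15, together 0.29 (upper quartile 0.47), which does not decide it. Genotype, substrain and sample handling stay open.

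Flanking DNA of another strain, or linked changes, might alter genes near Pla2g12b. Within 10 Mb, 27 of 89 tested genes were called, 30.3% against 32.5% elsewhere (odds ratio 0.906, 95% interval 0.553 to 1.45, Fisher's exact p = 0.73). The interval argues against a large excess of calls, in that window only, and leaves a modest excess open. With close pairs summed, 6 of 89 were called, with an odds ratio of 0.677 (0.241 to 1.54, exact p = 0.47), chosen after seeing the data. That interval is also too wide to exclude a modest excess. Differences elsewhere in the genome, such as between C57BL/6 substrains, were not tested, would go with genotype in every comparison here, and stay open. Of the 3 strain genes reported here, Cyfip2 alone was called. The transcript level of a strain gene does not check its sequence, so this call does not show a difference in substrain. Tuft cell and gasdermin C genes could reflect a type 2 response of the epithelium, as in worm infection, where goblet cell genes rise too. The goblet list median was -1.35, with 14 of 17 genes lower, which goes against that as the whole account. Retnlb of that list was at 1.47 without a call. Goblet genes fell along with Paneth and immune genes, so a type 2 response beside that fall is not excluded.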
